A study of Xenopus tropicalis with 26 samples.

How the data were processed

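H3K4me1 ChIP-seq peak lists and a table of gene expression in single embryos of Xenopus tropicalis were used as deposited. The labels describe 11 ChIP samples and 15 single-embryo RNA samples, all at stage 10.25 and 7 hours after fertilisation. Each ChIP sample was dissected from 100 fixed embryos and precipitated with 3 ug of antibody, per the labels' protocols. The alpha-amanitin samples received 5 pg per the labels, and the morpholino sample a mixture against Vegt, Otx1 and Foxh1. Samples were assigned to layers, treatments and clutches from their titles, and the mapping, tests and alternatives were fixed before the data were examined, except where the text says otherwise.

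Bowtie2 2.2.7 is named for all samples and RSEM 1.2.12 for the RNA samples, per the submitters' processing notes. The peak caller, its settings and the genome build are not given in the sources used here. For each peak, the authors deposited a fold enrichment (a ratio over background), a −log10 p, a −log10 q and a score in the 10-column narrowPeak layout. These values are the authors' own and were used only to describe, rank and filter peaks within a list. No −log10 p in any deposited list lay under 9. The 4 set 1 samples gave 2 lists, called on pooled replicates per the peak names, and the numbering of their peaks runs to 35831 and 43181 with gaps, as after a removal of peaks. The 7 set 2 samples gave a list each, numbered without gaps, and whether these were filtered is not given in the sources used here. Median peak widths ran from 299 to 536 bp, and 85.3% to 96.0% of peaks lay on the 10 chromosomes, the rest on scaffolds. Whether input libraries entered the calling is not given in the sources used here.

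The expression table holds TPM values, deposited by the authors for 26550 gene models in 15 columns, 1 per embryo, and all columns were used. The libraries were made by Smart-seq2 and tagmentation per the labels' protocols, and TPM keeps no record of depth, so the number of reads per embryo is unknown. Values were used without rescaling.

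Peaks were called shared when they overlapped by at least 1 bp. Chance overlap was the mean over 100 circular shifts of the second list, each chromosome and scaffold moved by its own random distance. Peaks of a single layer were untreated set 2 peaks that overlapped no peak of the other untreated set 2 layers. Peak strength was the rank of the authors' −log10 q within a list, in 5 bins of equal size, and differences over bins are unweighted means with normal 95% intervals. Lists of equal length hold the strongest peaks, as many as the shortest list of the comparison has. Alternatives were an overlap of 50% of the shorter peak, peaks within 500 bp, the upper 50% of each list by −log10 q, lists of equal length and, in ectoderm and mesoderm, only untreated peaks also present in set 1. Added after seeing the data were the comparison of layer pairs and its alternatives, bins with at least 20 peaks of both kinds, the look-up of single-layer and 3-layer peaks in set 1, endoderm peaks that recur in set 1, single-layer peaks also absent from the set 1 lists of the other layers, and peaks of the 10 chromosomes alone.

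For expression, limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust) was fitted to log2(TPM + 1) of all 15 embryos, over genes with a mean of at least 1 TPM. Differences are on this scale, which understates the change of low genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in the moderated F-test and in each pairwise contrast. Variation within a clutch was the standard deviation over the mean of TPM in its 5 embryos, for genes with a mean of at least 5 TPM. The share of variance between clutches came from one-way random effects per gene, with negative estimates set to 0. Alternatives were pseudocounts of 0.1 and 5, no filter or means of at least 10 or 20 TPM, quantile normalization, median-ratio scaling, eBayes without trend and robust, the sample number as a block, and leaving out each embryo. The distance of embryos to their clutch was added after seeing the data, with its alternative. Overlaps and variances were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

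The steps named here were tested on simulated data. The overlap step and the count of neighbouring peaks each gave 0 wrong calls for 4000 simulated peaks. Differences over strength bins averaged -40.001 points for a true -40 over 200 simulations, with 97% of intervals holding the true value. In a simulation of clutch C against clutch A over 12412 genes, the limma step recovered 42% of 50 genes changed 1.25-fold, 84% of those changed 1.5-fold, 88% of those changed 2-fold and 94% of those changed 4-fold, with 11 false calls. For 4000 simulated genes with true shares of 20%, 50% and 80%, the median share of variance between clutches came out at 10.9%, 39.4% and 74.2%, so with 3 clutches this median lies below the true share. A true coefficient of variation of 10% over 4000 simulated genes gave a median of 9.21% in 5 embryos, and a true embryo distance of 0.0754 gave 0.0756. For the test of clutch axes, which takes the share of the variance within clutches along a difference between clutches, permuted axes were exceeded in 4% of 50 simulations with independent genes and no relation, but in 94% with correlated genes and no relation. Axes that also carried the chance error of the clutch means were exceeded in 0% of the latter and in 76% of simulations with a true relation. This second reference was added after seeing the data.

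The rule for named genes asked for a gene symbol. The reference gene table given for this series covers assembly UCB_Xtro_10.0, and 0 IDs of the expression table matched it. The rule was applied without the symbol, and only the 2 IDs that were highest and the 2 that were lowest in a clutch are printed. None of the reference coordinates were used, since the build of the peaks is not given in the sources used here. Named regions are the 5 strongest of each class by rule, of which the text prints a few, and coordinates count from 1. Left out for want of gene names or of a shared build were the genomic location of peaks, marked members of the gene lists fixed in advance, tests of those lists between clutches, and the variation of marked genes and of those lists.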

Results

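H3K4me1, the monomethylation of histone H3 on lysine 4 that marks enhancers and the flanks of promoters, was mapped by ChIP-seq in the germ layers of Xenopus tropicalis gastrulae (Nieuwkoop-Faber stage 10.25, 7 hours after fertilisation). Chromatin came from animal cap tissue (ectoderm), marginal zone tissue (mesoderm) and vegetal tissue (endoderm), each dissected from 100 embryos. In the first experiment, called set 1 here, ectoderm and mesoderm of untreated embryos were profiled in 2 replicates each, and 1 pooled peak list was deposited per layer. In the second experiment, set 2, there was 1 library per layer and condition: untreated and alpha-amanitin-injected ectoderm, mesoderm and endoderm, and endoderm of embryos injected with morpholinos against Vegt, Otx1 and Foxh1. In addition, polyadenylated RNA of 15 single embryos from 3 clutches (A, B and C, 5 embryos each) was sequenced at the same stage.

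The set 1 lists held 13130 ectoderm and 15925 mesoderm peaks. The untreated set 2 lists held 4148 peaks in ectoderm, 8812 in mesoderm and 3740 in endoderm. After alpha-amanitin, an inhibitor of RNA polymerase II, 3206 ectoderm, 3648 mesoderm and 2372 endoderm peaks were listed, and the morpholino endoderm list held 1192. Read numbers behind these lists are unknown, so the lengths of the lists may differ with sequencing depth as well as with the mark. The set 2 conditions had no replicates, and no p-value is given for any comparison of peaks. Intervals on shares of peaks are exact 95% Clopper-Pearson intervals and cover counting error only.

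The first question was how far the mark differed between ectoderm and mesoderm. In set 1, 7977 of the 13130 ectoderm peaks overlapped a mesoderm peak (60.8%, 95% interval 59.9 to 61.6), and 7809 of the 15925 mesoderm peaks overlapped an ectoderm peak (49.0%, 48.3 to 49.8). The remaining 5153 ectoderm and 8116 mesoderm peaks had no counterpart. Random shifts of the other list along each chromosome gave overlaps of 2.12% and 1.69% on average. The region with the highest authors' −log10 q among the shared ectoderm peaks lay on chromosome 2 (102131103 to 102131954) and was in no set 2 list. The strongest mesoderm peak without an ectoderm counterpart lay on chromosome 1 (144393717 to 144394276), and it was also found in untreated mesoderm and in untreated and alpha-amanitin endoderm of set 2. The genome build of the coordinates is not given in the sources used here, so no gene is assigned to any region.

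In set 2, the single untreated endoderm list stood apart from those of the other layers. No further untreated endoderm list was analysed here, so a property of that library cannot be told apart from one of the layer. Merging the 3 untreated lists gave 11525 regions, of which 4832 were in mesoderm only, 1903 in endoderm only and 909 in ectoderm only. Ectoderm and mesoderm alone shared 2190 regions, mesoderm and endoderm alone 871, and ectoderm and endoderm alone 20, while 800 regions were in all 3 layers. Peaks of a single layer made up 21.9% (20.7 to 23.2) of the ectoderm list, 54.8% (53.8 to 55.9) of the mesoderm list and 50.9% (49.3 to 52.5) of the endoderm list. These shares moved with the lengths of the lists. With the 3740 strongest peaks of each layer, single-layer peaks made up 42.4% of ectoderm, 36.6% of mesoderm and 63.7% of endoderm peaks, so that mesoderm passed from the highest share to the lowest.

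Set 1 gave an independent view of these single-layer peaks in ectoderm and mesoderm. Of the 909 ectoderm-only peaks of set 2, 67.8% (64.6 to 70.8) were found in the set 1 ectoderm list, but 52.7% (49.4 to 56.0) were also found in the longer set 1 mesoderm list. Of the 4832 mesoderm-only peaks, 59.6% (58.2 to 61.0) were in the set 1 mesoderm list and 43.5% (42.1 to 44.9) in the set 1 ectoderm list. Endoderm-only peaks were found in set 1 mesoderm in 36.6% (34.5 to 38.8) and in set 1 ectoderm in 9.51% (8.23 to 10.9) of cases. A set 1 endoderm list was not analysed here.

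Alpha-amanitin injection addressed which peaks form without zygotic transcription. The untreated set 2 samples are titled wild type, and no sample is labelled as mock-injected or as given a control morpholino. Effects of injection itself were therefore not separated from those of either treatment. After treatment, 48.3% (46.7 to 49.8) of the untreated ectoderm peaks, 33.3% (32.3 to 34.3) of the mesoderm peaks and 29.4% (28.0 to 30.9) of the endoderm peaks were found again, against 0.589%, 0.473% and 0.256% with shifted lists. The mesoderm value moved most with the lengths of the lists: with both lists at the same number of strongest peaks, 53.7% (52.0 to 55.5) of ectoderm, 54.4% (52.8 to 56.0) of mesoderm and 34.6% (32.7 to 36.6) of endoderm peaks were found again. Equal lengths also take out any loss of the mark that shortened a list, so depth and loss cannot be separated here. The strongest endoderm peak that was missing after both alpha-amanitin and morpholino injection lay on chromosome 5 (81172596 to 81172967), with an authors' −log10 q of 43.5, and occurred in no other list. The strongest untreated endoderm peak, on chromosome 6 (116112302 to 116114513), with an authors' −log10 q of 121, was present in all 9 lists. The strongest mesoderm peak on a chromosome that was missing after alpha-amanitin lay on chromosome 2 (137808167 to 137808827).

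For ectoderm and mesoderm, the set 1 lists show how many peaks are missed between untreated samples of separate experiments. In the full lists, untreated set 1 held 77.8% (76.5 to 79.1) of the untreated set 2 ectoderm peaks and 70.5% (69.5 to 71.4) of the mesoderm peaks, 29.6 and 37.2 percentage points more than the shorter alpha-amanitin lists did. Of the 2146 ectoderm and 5876 mesoderm peaks missing after alpha-amanitin, 69.2% (67.2 to 71.2) and 63.4% (62.2 to 64.6) were in set 1. At lists of equal length, 48.3% (46.6 to 50.1) of the untreated set 2 ectoderm peaks were found in untreated set 1 ectoderm, 5.40 percentage points fewer than in alpha-amanitin ectoderm. For mesoderm, 50.9% (49.3 to 52.5) were found in set 1, 3.48 points fewer than after alpha-amanitin. The order of both comparisons thus turned with the lengths of the lists. The set 1 lists were called on 2 pooled replicates, and their peak numbers have gaps.

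Peaks of a single layer were found after alpha-amanitin less often than peaks of all 3 layers, and by the widest margin in endoderm. Of the 1903 endoderm-only peaks, 84 were found after alpha-amanitin (4.41%, 3.54 to 5.44), against 622 of the 838 endoderm peaks that were in all 3 layers (74.2%, 71.1 to 77.2). In ectoderm the shares were 27.3% (24.4 to 30.3) of ectoderm-only and 66.7% (63.4 to 69.9) of 3-layer peaks, and in mesoderm 15.6% (14.6 to 16.7) and 81.6% (78.8 to 84.2). Peaks in 2 layers lay in between, at 49.8% in ectoderm, 48.0% in mesoderm and 39.5% in endoderm. In ectoderm and mesoderm, the share of single-layer peaks found again was higher among stronger peaks, reaching 41.4% (28.6 to 55.1) and 38.6% (33.7 to 43.6) in the strongest of 5 bins. In endoderm it was 4.26% (2.54 to 6.64) in the weakest and 6.31% (3.84 to 9.68) in the strongest bin, where 90% (85.4 to 93.6) of 3-layer peaks were found. Averaged over 5 bins of equal peak strength, single-layer minus 3-layer peaks differed by -67.1 percentage points in endoderm (-70.3 to -63.9), -45.4 in mesoderm (-52.1 to -38.8) and -31.1 in ectoderm (-36.1 to -26.1). The weakest mesoderm bin held only 17 peaks of all 3 layers, and without it the mesoderm difference was -47.1. Peaks of all 3 layers were chosen for being found in several lists, and single-layer peaks were also found less often in untreated set 1. With set 1 at the length of the alpha-amanitin list, the difference was -17.4 points (-22.4 to -12.3) in ectoderm and -37.3 points (-44.0 to -30.6) in mesoderm, or -36.7 without the thin bin. The look-up of these peaks in set 1 was added after the data had been seen. With the full set 1 lists, these differences were -14.5 (-18.8 to -10.2) and -24.7 (-29.6 to -19.9). Of the 1903 endoderm-only peaks, 728 recurred in a set 1 list, and 61 of these were found after alpha-amanitin (8.38%, 6.47 to 10.6), against 74.97% (71.8 to 78.0) of 779 recurring 3-layer peaks, a difference of -64.1 points (-67.8 to -60.3) over the bins. Of the 1175 endoderm-only peaks absent from set 1, 1.957% (1.24 to 2.92) were found, and among these, peaks particular to the untreated library cannot be separated from those missing because of the treatment.

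**Figure D1:**
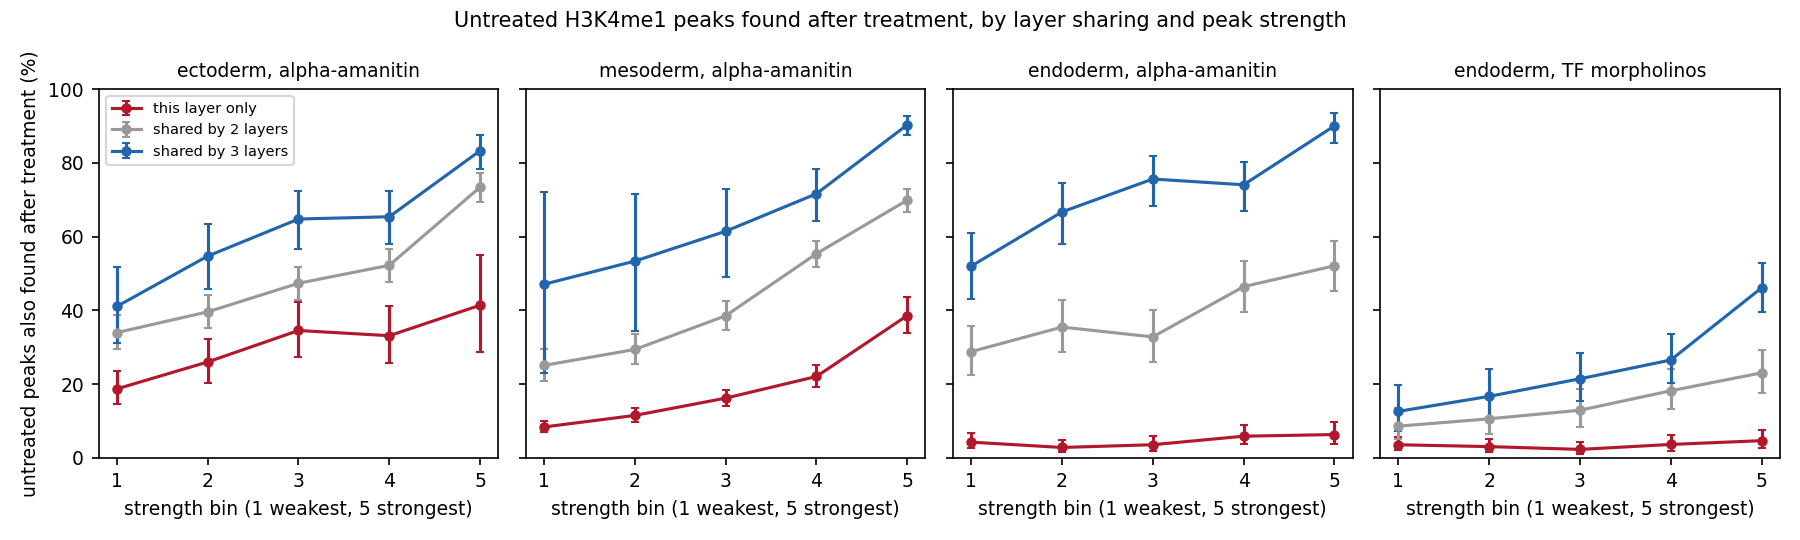
Share of untreated H3K4me1 peaks also found after treatment (y axis, percent) in 5 bins of the authors' −log10 q of the untreated peak (x axis), with exact 95% intervals. Each panel is a layer and treatment, and colours separate peaks of that layer only, of 2 layers and of 3 layers. Endoderm-only peaks stay at or below 6.31% after alpha-amanitin in every bin, while endoderm peaks of all 3 layers go from 52.0% to 90%.

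The endoderm list after alpha-amanitin overlapped mesoderm, and also ectoderm, more than the untreated endoderm list did. Of the 2372 alpha-amanitin endoderm peaks, 85.8% (84.4 to 87.2) lay in untreated mesoderm peaks, against 48.4% (46.8 to 50.01) of the untreated endoderm peaks. The untreated mesoderm list was the longest of set 2. At equal length, with 2372 and 3740 peaks per list, these shares were 51.9% and 33.4%. In untreated ectoderm peaks lay 51.6% (49.6 to 53.6) of the alpha-amanitin and 23.1% (21.8 to 24.5) of the untreated endoderm peaks. The alpha-amanitin list held 1272 peaks (53.6%, 51.6 to 55.6) that were absent from untreated endoderm. Of these, 80.8% (78.5 to 82.9) lay in untreated mesoderm peaks and 47.5% (44.7 to 50.3) in untreated ectoderm peaks. With 2372 peaks in every list, ectoderm and endoderm overlapped by 19.1% (17.6 to 20.8) without and 35.4% (33.4 to 37.3) with alpha-amanitin, and mesoderm and endoderm by 28.6% (26.8 to 30.4) and 45.9% (43.9 to 48.0). Ectoderm and mesoderm overlapped by 48.8% (46.7 to 50.8) and 48.0% (45.9 to 50.01). This comparison of layer pairs was chosen after the lists had been seen. With only peaks also in a set 1 list (2074 per list), ectoderm and endoderm overlapped by 24.4% without and 36.5% with alpha-amanitin. Mesoderm and endoderm then overlapped by 36.4% and 47.8%, and ectoderm and mesoderm by 50.1% and 48.6%. Both differences with endoderm were thus smaller among these peaks. At equal list lengths, mesoderm-only peaks were found in 8.15% (7.40 to 8.96) of cases in alpha-amanitin endoderm and in 8.88% (8.09 to 9.72) in alpha-amanitin mesoderm. In alpha-amanitin ectoderm it was 6.13% (5.47 to 6.84). Endoderm-only peaks were found in 4.41% of cases in alpha-amanitin endoderm, 0.631% (0.326 to 1.1) in alpha-amanitin mesoderm and 0.315% (0.116 to 0.685) in alpha-amanitin ectoderm.

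**Figure D2:**
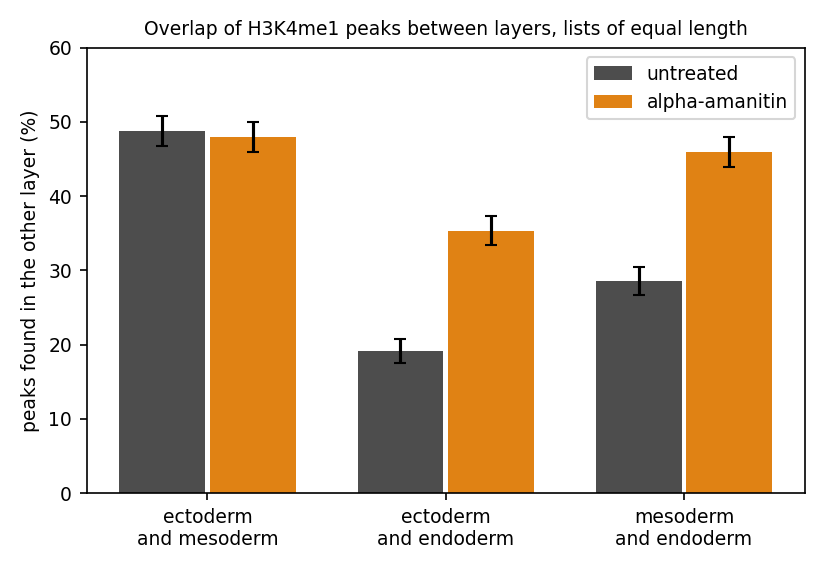
Share of H3K4me1 peaks found in the other layer (y axis, percent, mean of both directions) for the 3 pairs of layers, untreated and after alpha-amanitin, with the 2372 strongest peaks of each list. Bars start at 0 and error bars are the mean bounds of exact 95% intervals. Both pairs with endoderm are higher after alpha-amanitin (35.4% and 45.9%) than without it (19.1% and 28.6%).

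Few untreated endoderm peaks were in the list after morpholinos against Vegt, Otx1 and Foxh1, maternal transcription factors with known roles in endoderm and mesendoderm formation. Of the 3740 peaks, 441 were found again (11.8%, 10.8 to 12.9), against 0.236% with a shifted list. At equal length, 19.3% (17.1 to 21.7) of peaks were found. Endoderm-only peaks were found in 3.36% (2.60 to 4.27) and 3-layer peaks in 27.2% (24.2 to 30.4) of cases, a difference of -21.2 points (-24.1 to -18.3) over the strength bins. The difference was -41.2 with lists of equal length. The strongest peak of the morpholino list that was absent from untreated endoderm and lay on a chromosome was on chromosome 9 (26455262 to 26455572) and was also in set 1 mesoderm. The morpholino list was the shortest and had the smallest share of its peaks on the 10 chromosomes, 85.3% against 96.0% for untreated endoderm. Of its 1192 peaks, 37.1% (34.3 to 39.9) lay in untreated endoderm peaks and 59.2% (56.4 to 62.0) in peaks of the longer untreated mesoderm list. Its length alone limits the share of untreated peaks found. With 1 library, depth and loss of the mark cannot be separated here.

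Endoderm peaks missing after the morpholinos were mostly also missing after alpha-amanitin. Of 3299 peaks missing after morpholinos and 2639 missing after alpha-amanitin, 2498 were missing after both, where independent losses would give 2328. Both lists held 300 of the untreated peaks, against 130 for independent losses. Alpha-amanitin losses made up 75.7% (74.2 to 77.2) of the peaks missing after morpholinos and 32.0% (27.6 to 36.5) of those found, a difference of 38.8 points (33.6 to 44.0) within bins of peak strength. Both treatments were set against the same untreated library, so part of the excess may come from peaks particular to that library. Peaks shared between layers were also found more often after either treatment. Endoderm-only peaks were found in 4.41% of cases after alpha-amanitin and 3.36% after morpholinos, and 3-layer peaks in 74.2% and 27.2%. Neither the values for independent losses nor the strength bins allow for this sharing, so part of the excess may come with it.

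The single-embryo RNA-seq asked how much expression varies among sibling embryos and among clutches. The 15 embryos fell into their 3 clutches. The first principal component (45.1% of the variance over 10011 genes) separated clutch C from A and B, and the next (25.8%) separated A from B. Correlations across genes of log2 values had a median of 0.987 for embryos of one clutch (0.974 to 0.991, 30 pairs) and 0.947 for embryos of different clutches (0.936 to 0.964, 75 pairs). The lowest pair within a clutch lay above the highest between clutches. No pair of embryos had identical values.

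**Figure D3:**
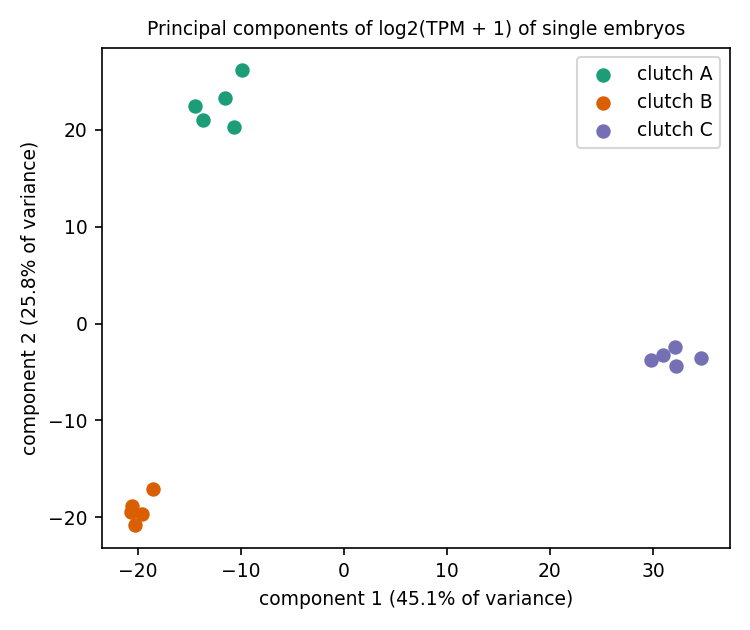
Principal components 1 (x axis, 45.1% of variance) and 2 (y axis, 25.8%) of log2(TPM + 1) over 10011 genes, with 1 point per embryo coloured by clutch. The 5 embryos of each clutch lie together and apart from the other 10.

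Of 12551 genes tested, 7264 (57.9%) differed among clutches in the moderated F-test of limma at an adjusted p under 0.05, and 1057 of these differed by at least 2-fold between a pair of clutches. Clutch B against A gave 3211 genes (1784 higher and 1427 lower in B), clutch C against A 5216 (2283 higher, 2933 lower in C) and clutch C against B 6033 (2491 higher, 3542 lower in C). Most differences were small. The median size among called genes was 0.39 on the log2(TPM + 1) scale for B against A, 0.40 for C against A and 0.41 for C against B, and 346, 672 and 714 genes passed 2-fold. The 5 embryos of clutch C did not overlap the other 10 in 2129 genes (16.96%), those of clutch B in 1119 (8.92%) and those of clutch A in 762 (6.07%), where chance gives 0.0666%. Scaling by median ratios made the higher calls the larger part in clutch C (52.3% against 43.8% for C against A, 50.7% against 41.3% for C against B), so no direction of the whole is given. There was 1 set of siblings per clutch, so parents, fertilisation and handling cannot be separated.

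The gene models of the expression table carry no gene symbols, and 0 of the 26550 IDs matched the reference gene table, so genes cannot be named and gene groups were not tested. The model Xetrov90029531m.g was present at 40.3 ± 7.098 TPM (SD, n = 5) in clutch C and listed at 0 in all 10 embryos of clutches A and B (limma F-test adjusted p = 3.18e-16). The model Xetrov90011688m.g was at 42.4 ± 5.04 TPM (SD, n = 5) in clutch C and at most 0.42 TPM in any other embryo (limma adjusted p = 1.19e-15). Of models that were low in one clutch, Xetrov90020226m.g was listed at 0 in all embryos of clutch A, with 47.5 ± 2.91 TPM in B and 50.4 ± 6.24 TPM in C (SD, n = 5 each; limma adjusted p = 8.81e-18). The model Xetrov90026308m.g was at 2.17 ± 1.3 TPM in clutch B, against 162 ± 18.3 in A and 122 ± 6.42 in C (SD, n = 5 each), a log2 difference of -5.57 (SE 0.17; limma adjusted p = 3.42e-12) with all 5 embryos of B below the other 10.

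Sibling embryos were alike in most genes. Over 10011 genes with a mean of at least 5 TPM, the median coefficient of variation among the 5 embryos was 9.19% in clutch A, 7.86% in B and 8.12% in C. It was below 10% in 56.3%, 65.0% and 63.2% of genes, and above 50% in 1.44%, 0.829% and 0.849%. Variation was larger at low expression. Genes at 1 to 5 TPM had medians of 26.7%, 24.1% and 24.2%, and genes at 100 TPM or more 6.71%, 5.51% and 5.80%. The variance between clutches made up a median of 52.6% of the variance of a gene (quartiles 21.2% and 75.8%, jackknife SE 4.99 over embryos). This SE does not cover the sampling of clutches, of which there were 3, and in simulations the median lay below the true share. The variance within clutches also holds technical variation between libraries, which was not separated. The share between clutches was over 50% in 5260 genes and 0 in 1217. The comparison of marked with unmarked genes that the design names was not run, because peaks could not be tied to gene models here.

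**Figure D4:**
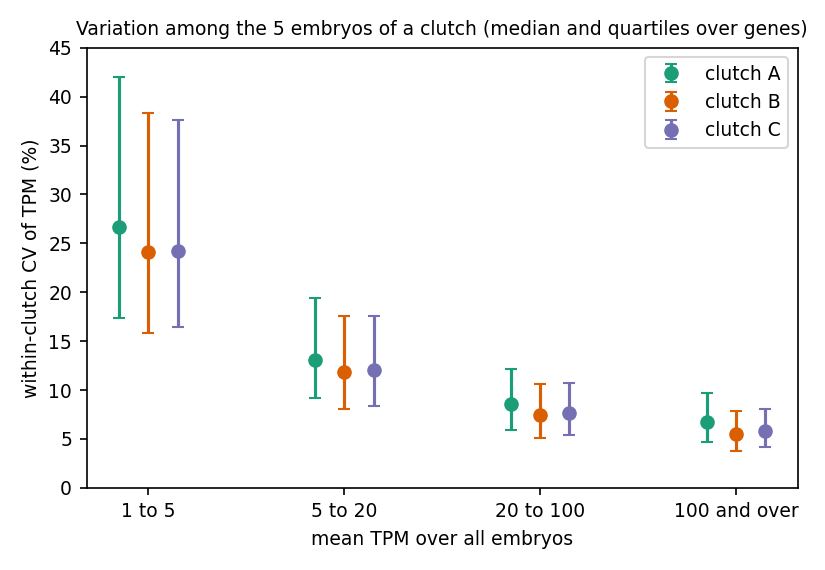
Coefficient of variation of TPM among the 5 embryos of a clutch (y axis, percent) in 4 ranges of mean TPM (x axis), with points for the median and bars for the quartiles over genes. Medians go from 24.1% to 26.7% at 1 to 5 TPM down to 5.51% to 6.71% at 100 TPM or more.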

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

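The tests in this part that were chosen only after the result was seen are those of peak strength, of peaks recurring in set 1 and of marginal zone tissue for endoderm-only peaks, and the comparison with set 1 in ectoderm and mesoderm at equal list lengths and by kind of peak.

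In 27 sets of 5 embryos (10 measures per embryo or gene, in each clutch where they varied), 3 had an embryo whose distance to the nearest sibling took more than 0.71 of the whole range. Chance alone gives about 1 in 20 for values that vary freely, which does not apply to 2 of the 3, where the siblings lay at or near 0 and almost any higher value meets the criterion. The most abundant gene model was at 41208.5 TPM in sample 1 of clutch B and between 21506.1 and 24175.4 TPM in its siblings. Xetrov90011688m.g was at 0.24 TPM in sample 1 of clutch A, with its siblings listed at 0, and at 0.42 TPM in sample 3 of clutch B, with its siblings at 0.07 TPM or less. Both of these values lie far below the level in clutch C.

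Endoderm-only peaks were found after alpha-amanitin in 4.41% of cases, against 74.2% for endoderm peaks of all 3 layers. Peak strength cannot be the whole cause: in the strongest of 5 bins the 3-layer peaks were found more often by 83.7 percentage points. With lists of equal length the margin over the strength bins was 68.5 points, so it does not rest on unequal lengths alone. The alpha-amanitin list was the shortest, though, and that cut left it unchanged. A shallow library behind this list therefore stays open as part of the cause. Peaks particular to the single untreated endoderm library cannot be the whole cause among peaks that recurred in set 1, where the margin was 64.1 points (60.3 to 67.8). Set 1 here holds ectoderm and mesoderm lists only. Such peaks stay open as a cause for the 1175 endoderm-only peaks absent from set 1, of which 1.957% were found. The choice of 3-layer peaks for being found in several lists also stays open as part of the margin. In untreated set 1 at equal length, this choice came with differences of -17.4 points in ectoderm and -37.3 in mesoderm. For endoderm no such comparison was at hand. Marginal zone tissue in the alpha-amanitin endoderm sample may contribute. At equal list lengths, mesoderm-only peaks were found there at 0.918 of their rate in alpha-amanitin mesoderm (8.15% against 8.88%). They were also found in 6.13% of cases in alpha-amanitin ectoderm, so finding them is not particular to the endoderm sample. In the full alpha-amanitin mesoderm list their rate was 15.6%. Endoderm-only peaks were found in alpha-amanitin endoderm more often (4.41%) than in alpha-amanitin mesoderm (0.631%). With 1 library, a mixture of tissues therefore cannot be told apart from endoderm that lacks these peaks. A dependence of endoderm-only marking on zygotic transcription and an effect of injection itself also stay open and were not tested apart from these.

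Whether the ectoderm and mesoderm peaks missing after alpha-amanitin exceed those missing between untreated samples of the 2 experiments turned with the lengths of the lists. At equal list lengths, the share of untreated set 2 peaks found after alpha-amanitin was higher than the share found in untreated set 1, by 5.40 points in ectoderm and 3.48 points in mesoderm. In the full lists it was lower, by 29.6 and 37.2 points, and 69.2% and 63.4% of the peaks missing after alpha-amanitin were in set 1, whose lists were longer and called on pooled replicates. A difference as between experiments and an effect of alpha-amanitin therefore cannot be told apart, since no comparison here separates the depth of a library from a loss of the mark. Single-layer peaks were found less often than 3-layer peaks in untreated set 1 too (-17.4 points in ectoderm and -37.3 in mesoderm at equal length, -14.5 and -24.7 in the full lists) and by a wider margin after alpha-amanitin (-31.1 and -45.4, with overlapping intervals only for mesoderm at equal length), so an effect on part of the single-layer peaks stays open.

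The differences among clutches were set against other groupings of the same embryos. Of 100 drawn splits into 3 groups of 5, only 1, the real one, gave as many genes (7264, against at most 1746 in the others). For the pairs of clutches, the real split was again the only 1 of 100 with as many genes: 3211 against at most 484 for B and A, 5216 against at most 150 for C and A, and 6033 against at most 724 for C and B. Chance is thus unlikely for each, though 100 splits cannot give a share under 1 in 100. The other splits mixed the clutches, which widens the spread within their groups and lowers their counts. A few abundant genes shifting the TPM of all others cannot be the cause of the count, since 7233 genes were called after median-ratio scaling. Differences in parents, fertilisation, handling or library batch between clutches stay open and were not tested.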

How the results depend on the processing

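The alternatives added after seeing the data were the restriction to the 10 chromosomes, those for layer pairs, thin bins and set 1 absence, the look-up of kinds of peak in set 1, endoderm peaks recurring in set 1, the reference for clutch axes, and the TPM filter for embryo distances. Of 310 alternative values, 254 kept the main result. For shares and for differences between shares of peaks, this means within the interval or spread of the main value. For counts it means within 1.5-fold, and for other tested differences the same direction and side of the threshold. The other 56 moved out of the interval, and all of them were shares of peaks or differences between such shares. Reversal was looked for only in differences, where 0 reversed. It was not looked for in shares of peaks, and the order of some of these turned with the lengths of the lists. The sizes of the log2 differences of the 3 named models near 0 in a clutch moved with the pseudocount: for pseudocounts of 0.1 and 5, from 5.35 to 8.64 and 3.16 for Xetrov90029531m.g, from 5.34 to 8.23 and 3.22 for Xetrov90011688m.g, and from -5.64 to -8.93 and -3.43 for Xetrov90020226m.g, as the log scale near 0 sets them. The shares of peaks moved with the overlap rule and with the lengths of the lists, by their construction. For other moves the cause was not tested.

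With the upper 50% of each list by −log10 q, 57.9% of set 1 ectoderm peaks were in mesoderm, 56.9% of endoderm peaks were endoderm-only, 40.1% of ectoderm, 30.8% of mesoderm and 26.4% of endoderm peaks were found after alpha-amanitin, and 10.2% after morpholinos. With lists of equal length these were 55.7%, 63.7%, 53.7%, 54.4%, 34.6% and 19.3%. With an overlap of 50% of the shorter peak, the first 4 were 59.5%, 53.1%, 46.0% and 32.0%. With peaks within 500 bp the 6 values were 66.7%, 44.9%, 58.3%, 42.2%, 35.4% and 15.7%, and the difference between endoderm-only and 3-layer peaks over strength bins was -73.7 points. Among untreated peaks also present in set 1, 54.0% of ectoderm and 40.01% of mesoderm peaks were found after alpha-amanitin. The margin for peaks missing after both endoderm treatments stayed between 38.8 and 40.1 points. All 14 values with the 10 chromosomes alone stayed within their intervals.

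All 92 alternative counts of genes differing among or between clutches lay within 1.5-fold of the main count: for the F-test 5290 to 7702 genes, or 6771 to 7213 without each embryo in turn. The share of variance between clutches lay between 50.4% and 53.1%, or 51.01% and 54.9% without each embryo. The sample numbers did not pair the embryos: same-numbered embryos of different clutches had residual correlations of -0.139 to 0.2002 over 15 pairs, and 5 of 15 embryos correlated best with their own number. With the sample number as a replicate block, 7055 genes were called, and 3090, 5041 and 5894 in the pairs B and A, C and A, and C and B. Of the 7264 genes called without the block, 6852 were called with it.

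Not run were the genomic location of peaks, marked members of the gene lists fixed in advance, gene list tests between clutches, and the within-clutch variation of marked genes and of those lists, with their alternatives, since 0 gene models matched the names used here and no annotation of a stated build was at hand. No limit from depth is given, since neither peak lists nor TPM keep read numbers.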

Other observations

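The embryo distances and the chance error in the clutch axes were chosen only after the data had been seen, and the tests of clustered peaks and of permuted axes were set before their results.

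Peaks that occurred only after treatment were often known from other samples. Of the 1177 alpha-amanitin ectoderm peaks absent from untreated ectoderm of set 2, 72.5% (69.8 to 75.01) were in set 1 ectoderm, and of the 516 such mesoderm peaks 59.7% (55.3 to 64.0) were in set 1 mesoderm. Of the 750 morpholino endoderm peaks absent from untreated endoderm, 43.9% (40.3 to 47.5) lay in untreated set 2 mesoderm and 19.2% (16.4 to 22.2) in alpha-amanitin endoderm. Only 128 of the 3740 untreated endoderm peaks were found in all 9 lists. On single chromosomes, the share of endoderm peaks found after alpha-amanitin went from 25.3% (21.1 to 29.9) on chromosome 6 to 33.6% (24.8 to 43.4) on chromosome 10, with overlapping intervals. In mesoderm it went from 27.8% (23.0 to 33.0) on chromosome 10 to 37.3% (34.6 to 40.05) on chromosome 1, with intervals that did not overlap, and in ectoderm from 42.8% (34.6 to 51.2) on chromosome 10 to 54.4% (46.3 to 62.3) on chromosome 9, with overlapping intervals. These were the lowest and highest of the 10 chromosomes in each layer, and the intervals make no allowance for that choice. Mesoderm-only peaks made up 59.3% of the mesoderm peaks on chromosome 10 and 52.8% on chromosome 1.

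Clutches differed in some genes as if by presence or absence. In 15 gene models, all 5 embryos of a clutch were at 0.1 TPM or less and the other 10 at 5 TPM or more, or the reverse: 3 were near 0 and 6 present only in clutch C, 2 and 2 in clutch B, and 1 and 1 in clutch A. Genes that varied among siblings of one clutch tended to vary in the others. After removal of the trend with expression in 20 bins, Spearman's correlation of the coefficient of variation across 10011 genes, which are not independent replicates, was 0.457 for A and B, 0.366 for A and C and 0.337 for B and C. The median absolute log2 difference of an embryo to the mean of its siblings was 0.106 ± 0.0191 in clutch A, 0.0902 ± 0.0217 in B and 0.0939 ± 0.0120 in C (SD, n = 5). The 3 two-sided exact permutation tests between clutches gave p = 0.262 for A and B, 0.270 for A and C and 0.746 for B and C (Benjamini-Hochberg adjusted 0.405, 0.405 and 0.746).

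A hypothesis was that clustered peaks, with at least 2 other peaks within 25 kb, are found after alpha-amanitin more often than isolated ones only because they are stronger. Within bins of strength, clustered peaks were still found more often by 14.3 points in ectoderm (10.8 to 17.9), 11.4 in mesoderm (8.91 to 13.9) and 10.2 in endoderm (6.83 to 13.5), which goes against strength as the whole cause. Among single-layer peaks alone the margin was 7.02 points in ectoderm (-1.06 to 15.1), 6.56 in mesoderm (3.26 to 9.86) and -0.262 in endoderm (-2.57 to 2.04). Single-layer peaks made up 16.2% of clustered and 33.9% of isolated peaks in ectoderm. In mesoderm these shares were 49.9% and 70.6%, and in endoderm 43.3% and 62.4%. The margin may therefore come with the sharing of peaks between layers in endoderm, and at least in part in ectoderm and mesoderm.

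A further hypothesis was that embryos of one clutch differ along the same genes as the clutches do. The axis of clutch C against the mean of A and B held 0.494% of the variance within clutches, and the axis of B against A 0.452%. Both lay above the highest of 2000 axes permuted among genes of like variation (0.122% and 0.152%), but simulations showed that correlated genes alone exceed such axes. When permuted axes also carried the chance error of the clutch means, with the correlation of the genes kept, 51.7% of them held as much for C against A and B and 83.95% for B against A. The values were therefore no larger than this error alone gives, and the test gives no evidence for the hypothesis.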
